A study of Homo sapiens with 6 samples.

How the data were processed

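RNA from 6 groups of human cells, each carrying a stable shRNA, was measured on 1 Affymetrix whole-transcript array per group. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase, and 200 ng were amplified with the Ambion WT Expression Kit and labelled with biotin. The deposited values are on the log2 scale, a scale read from their range and from the method named, and were made with oligo and RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes, without versions. Whether all 6 arrays were normalized together, the probe annotation used and the genome build are not given in the sources used here. The array medians differed between the pairs, at 7.72 and 7.74 in H1, 7.34 and 7.29 at day 8 and 7.19 and 7.18 in HUVEC. Exactly equal values occurred only within pairs. Both argue against a joint normalization of all 6 arrays. Differences within a pair were therefore the main results, and differences between cell states were also computed after other scalings.

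Probe sets were named through the platform annotation, with symbols updated through Entrez identifiers and a RefSeq gene table of assembly GRCh38.p14, used for names only. Of 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 had none in that annotation. Several or no symbol left a probe set out of the gene comparisons. For 31 probe sets the Entrez identifier was not in the gene table, and these kept the annotation's symbol. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays, which gave 18394 genes. XIST and Y-linked genes were left out. A gene entered a comparison where the higher of its values on the 2 arrays reached the 40th percentile of all probe sets on that array.

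With 1 array per group there were no replicates and no test was possible, so each comparison gives the log2 difference per gene (lncRNA shRNA minus control shRNA, or 1 cell state minus another), with counts of genes at or beyond 2-fold and, for the lncRNA pairs, 1.5-fold. For the lncRNA pairs, the spread of differences among the dim genes that did not enter is given as a description of array scatter, not as an error. The precision of each value is unknown.

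The 29 gene lists fixed before the data were examined covered cell types (pluripotency, primitive streak and early mesoderm, endoderm, neuroectoderm, trophoblast and amnion, cardiac, endothelial, blood, smooth muscle and pericyte, fibroblast and matrix), pathways (adhesion and integrins, angiogenesis and VEGF response, Notch and arteriovenous, TGF-beta and BMP, WNT, HOX genes, NF-kB, interferon, p53), the cell cycle (G2/M, S phase, replication-dependent histones), and metabolism and stress (immediate early, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and ATF4 response, ribosomal proteins, oxidative phosphorylation, reference genes). Some genes belong to several lists. The median difference of a list was set against the medians of 10000 random lists of equal size matched on mean expression in 20 bins. Its percentile describes these arrays and is not a p-value. For each lncRNA pair, the 200 genes highest and the 200 lowest between the control arrays of the other cell states served as further lists.

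Genes were named by a rule fixed before the data were examined. It took the 12 highest and 12 lowest differences of each lncRNA pair that reached 1.5-fold and the 8 highest and 8 lowest of each control comparison, leaving out genes whose probe sets disagreed in sign and symbols with the usual prefixes of small RNAs and unnamed loci, which did not cover the small nuclear RNA gene RNVU1-15, and up to 4 members of each list with the largest differences. Exceptions chosen after their values were seen are the genes shared between pairs and those named in the closing observations. The targets and their neighbours were also reported. In the gene table ALIEN was an alias of 2 genes, the lncRNA LINC00261 and the protein-coding gene COPS2, of which the lncRNA was taken, PUNISHER an alias of 1, the lncRNA AGAP2-AS1, and TERMINATOR of 0.

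Alternatives fixed in advance were 3 other scalings (each array centred on its median, quantile normalization over the 6 arrays, and loess of each pair), no filter or a 60th percentile filter on dim genes, the mean of a gene's probe sets, random lists without matching, lists of 100 genes between cell states, and overlaps at 2-fold. Chosen after seeing the data were counts without small RNA genes, list medians of the TERMINATOR and ALIEN pairs as residuals on each other, and PUNISHER list medians without genes of equal value. The residuals cover only genes that entered both pairs, so a list can have fewer members there. Quantile and loess scaling used limma 3.58.1 in R 4.3.3. All other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

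The procedure was tested on simulated data with the genes of each pair, 13294 for TERMINATOR, 13303 for ALIEN and 13395 for PUNISHER. Of 100 genes raised by 2 on the log2 scale, 100 were recovered at 2-fold in each pair, and of 100 genes lowered by 1.5, 99, 99 and 100 were recovered, with 0 unchanged genes called. Of 100 lists of 20 genes without a shift, 9, 4 and 1 lay outside the random range, and of 100 lists shifted by 0.4, 100 did so in each pair. These simulations hold independent noise across genes, which real arrays need not have, and no equal values, which the HUVEC arrays have. Their noise had an SD of 0.23, 0.24 and 0.15, far below the changes put in, so recovery of single genes was nearly fixed in advance.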

Results

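Gene expression was measured on 6 whole-transcript arrays, 1 for each group of human cells carrying a stable short hairpin RNA (shRNA). H1, a human embryonic stem cell line, carried a control shRNA or an shRNA against the long non-coding RNA (lncRNA) TERMINATOR. Late vascular progenitors, differentiated from pluripotent stem cells for 8 days in a mesoderm-inducing medium with bFGF, VEGF and BMP4, carried a control shRNA or an shRNA against ALIEN. Human umbilical vein endothelial cells (HUVEC), primary cells from the lining of a vein, carried a control shRNA or an shRNA against PUNISHER. The submitters' labels attach the word scramble, the usual name of a control sequence, to every one of these shRNAs, and the groups follow the lncRNA or control named beside it. Each group had 1 array, so there were no replicates, no p-value was computed, and the number of arrays limits the precision. All differences are log2 values of the lncRNA shRNA array minus the control shRNA array of the same cells unless said otherwise, and all describe these arrays only.

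The array medians over 33297 probe sets were 7.72 and 7.74 for the H1 control and TERMINATOR arrays, 7.34 and 7.29 for the day 8 control and ALIEN arrays, and 7.19 and 7.18 for the HUVEC control and PUNISHER arrays. Within pairs, Pearson's r across probe sets was 0.992, 0.988 and 0.985. Exactly equal values on both arrays of a pair occurred for 348 probe sets in H1, 555 at day 8 and 11866, or 35.6%, in HUVEC, and for 0 probe sets between arrays of different pairs. Of the genes compared in HUVEC, 3755 had equal values, which holds many list medians of that pair near 0. Equal values hold the medians of its random lists near 0 too, so a small list median can lie outside the random range there. Genes of small nucleolar RNAs, short guides of RNA modification, differed as a class within each pair. Their median difference was 0.61 over 141 genes on the TERMINATOR array, -0.57 over 130 genes on the ALIEN array and 1.05 over 145 genes on the PUNISHER array. Genes of small nuclear RNAs, which take part in splicing, had medians of 0.75, -0.79 and 0.72. MicroRNA genes had medians of 0.03, -0.09 and 0.00.

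The control arrays describe the 3 cell states in which the lncRNAs were targeted. Because the array medians differed by -0.38 between day 8 and H1, by -0.54 between HUVEC and H1 and by -0.16 between HUVEC and day 8, differences between cell states are given after centring each array on its median. Centring does not remove other differences between arrays that were probably not normalized together. At day 8, LUM, a proteoglycan of connective tissue, was 7.37 higher than in H1, CRHBP, which binds corticotropin-releasing hormone, was 6.97 higher and LOX, which crosslinks collagen, was 6.76 higher. TM4SF1, EMP1, GNG11, SLITRK6 and HGF were 6.55, 6.34, 6.22, 6.20 and 5.96 higher. CRIPTO, a Nodal co-receptor of pluripotent cells, was lower at -7.65, and SOX2, a core pluripotency factor, at -5.49. ZNF676, PTPRZ1, USP44, ZNF826P, IDO1 and NMU were also lower, at -7.07, -6.78, -6.14, -5.48, -5.40 and -5.21. Many of the largest differences between cell states set a high value against a dim one. CRIPTO, for example, was at 3.70 at day 8, where the 40th percentile was 6.75. The exact size and rank of such differences are uncertain.

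As a group, 24 pluripotency genes had a centred median of -3.10 at day 8 against H1, while 27 endothelial genes had 2.23, 14 HOX genes, which pattern the body axis, 2.95, and 23 fibroblast and matrix genes 1.91. Genes of hypoxia and glycolysis stood at 1.55, cardiac genes at 0.58, genes of early mesoderm at 0.50 and S phase genes at -0.75. The Notch and WNT medians were -0.15 and -0.10 as deposited, but 0.23 and 0.28 after centring and also above 0 after quantile or loess scaling. By 2-fold, 911 genes were higher and 3746 lower of 13918 as deposited, against 1375 and 2114 after centring, 1582 and 1847 after quantile normalization and 1568 and 1698 after loess.

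HUVEC were set apart from H1 by vascular genes. MMP1, a collagenase, was 8.68 higher than in H1, LYVE1, a hyaluronan receptor of lymphatic and some other endothelium, 8.66 higher, and PECAM1, an adhesion molecule of endothelial junctions, 7.86 higher, all after centring. MMRN1, HHIP, MGP and SRGN were 8.17, 8.12, 8.12 and 7.65 higher, also after centring, and ARHGDIB was 7.17 higher as deposited. CRIPTO at -8.20, the surface protein CD24 at -7.67 and the pluripotency genes DPPA4 and LIN28A, both at -6.81, were lower, as were SLC7A3, LRRN1, GRPR and EPCAM at -6.89, -6.80, -6.67 and -6.61. The centred medians were 4.89 for 29 endothelial genes, -3.96 for 25 pluripotency genes, 2.51 for angiogenesis, 2.18 for HOX genes and -0.79 for G2/M genes. By 2-fold, 1365 genes were higher and 3454 lower of 14189 as deposited, while centring gave 2606 and 1848, quantile normalization 2106 and 2063, and loess 2126 and 2218, so that the larger side depended on the scaling.

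Against the day 8 control, HUVEC had higher levels of SRGN, a proteoglycan of secretory granules, at 7.58, and of MMRN1 and LYVE1 at 6.74 and 6.67. SULT1B1, HHIP, PALMD, MGP and SLFN11 were 6.53, 6.14, 6.01, 5.81 and 5.71 higher. LUM at -8.07, CRHBP at -7.65 and ACTC1, the actin of cardiac muscle, at -5.69 were lower, with SLITRK6, HAPLN1, CD24, ERVH48-1 and DSG2 at -6.13, -6.06, -5.67, -5.64 and -5.58. The centred medians were 1.96 for endothelial genes, 1.59 for interferon response genes, -0.74 for fibroblast and matrix genes, -0.99 for cardiac genes, -1.48 for TGF-beta and BMP response genes and -1.69 for hypoxia and glycolysis genes. By 2-fold, 1756 genes were higher and 1177 lower of 13913 as deposited, against 2401 and 967 after centring and 1168 and 1340 after loess, which put more genes on the lower side.

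**Figure D1:**
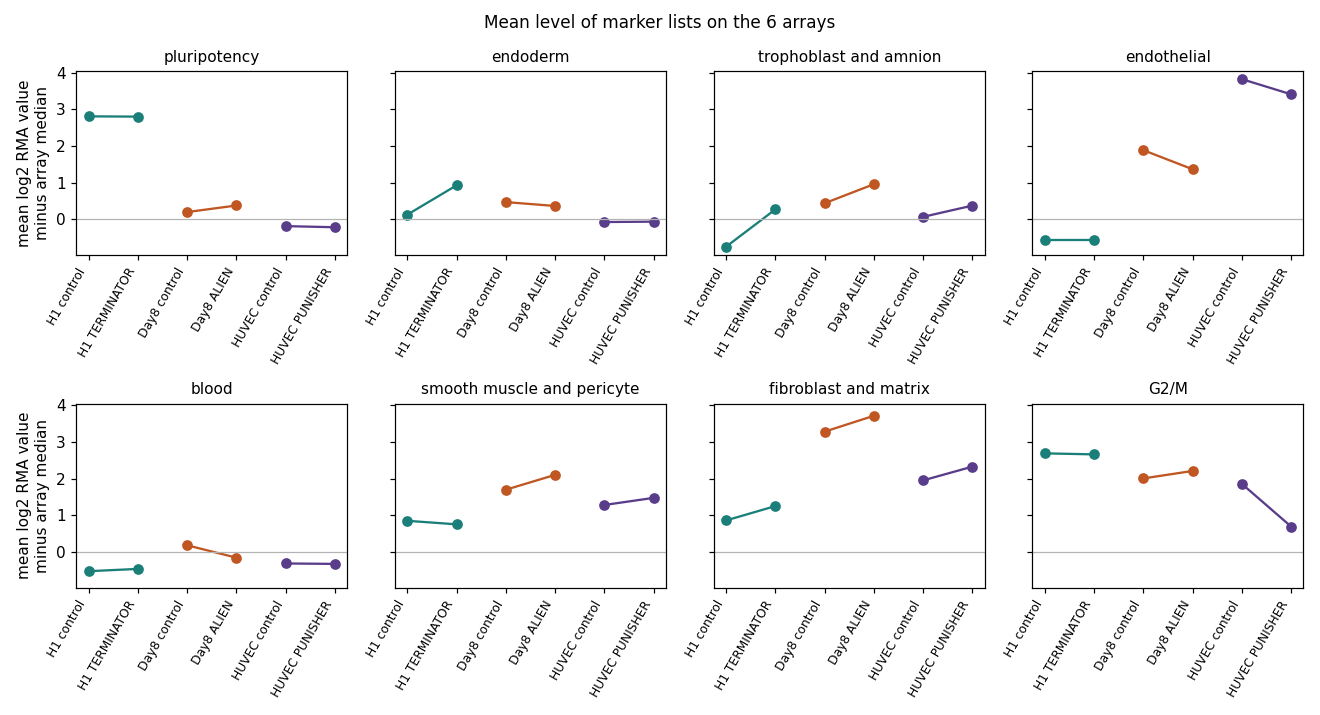
Each panel shows the mean log2 RMA value of a marker list minus the array's median on the 6 arrays, with 1 point per array and a line joining the control and lncRNA shRNA arrays of the same cells. The pluripotency mean was 2.81 in the H1 control against 0.20 at day 8 and -0.19 in HUVEC, and the endothelial mean was 3.82 in the HUVEC control against 1.88 at day 8.

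In the pairs below, 44 of the 87 list medians lay outside the central 95% of medians of 10000 random lists matched on expression, 16 for TERMINATOR, 15 for ALIEN and 13 for PUNISHER. None of these 44 medians had the other sign under any of the 3 other scalings.

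The H1 pair asked what lowering TERMINATOR did to pluripotent cells. The array's annotation named no probe set for TERMINATOR, so its own level was not analysed here, and the shRNA's effect on its target was not checked. LUM was 3.87 higher, from 5.26 to 9.13, AFP, a fetal serum protein of yolk sac and liver, 3.38 higher, from 6.43 to 9.81, and CGA, the alpha subunit of chorionic gonadotropin, 3.05 higher, from 6.27 to 9.32. MMP1 was 2.85 higher, the fibrinogen chain FGB 2.69, the thyroid hormone carrier TTR 2.69, the hypoxia factor EPAS1 2.34 and TFAP2A, a transcription factor of trophoblast and surface ectoderm, 2.34. HAPLN1, MEIS1, RBP4 and ACP3 were 2.14, 2.05, 2.00 and 1.98 higher. Lower values were smaller in size: the zinc finger gene ZNF99 was at -1.54, ESYT2 and ZNF729 at -1.11 each, and the neuropeptide Y receptor NPY5R at -1.04. The related receptor NPY1R was lower, from 9.20 to 8.20, as was PRICKLE1, of planar cell polarity, from 10.19 to 9.19. STK32A, ZNF492, ANKRD34B, LIMCH1, ZNF737 and EDA2R lay between -0.99 and -0.90.

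The pluripotency list had a median of -0.01 over 25 genes, inside the random range and with the other sign under some scalings. DPPA2 stood at -0.59 and SOX2 at 0.29. Trophoblast and amnion genes had a median of 0.97, with 9 of 13 higher by 1.5-fold, among them GATA3 at 1.45. The median was 0.80 with no filter on dim genes and 1.79 under the stricter filter. A gene enters by the higher of its 2 values, so a stricter filter favours raised genes over unchanged dim ones. Larger medians under it are no added support. Endoderm genes had a median of 0.36, with 7 of 16 higher, including the apolipoprotein APOA2 at 1.89 and the Nodal antagonist CER1 at 1.56, and this median was 1.49 under the stricter filter and 0.16 after the trend with the ALIEN pair across genes was removed. Cardiac genes had a median of 0.25, with 3 of 15 higher, HAND1 at 1.45, MYL4 at 1.20 and ISL1 at 0.97. TGF-beta and BMP response genes had a median of 0.24, with 6 of 22 higher, including TGFB2 at 1.47 and MSX2 at 1.05. Fibroblast and matrix genes stood at 0.18, with 3 of 19 higher and LOX at 1.12. WNT pathway genes stood at 0.14, with RSPO3, an enhancer of WNT signalling, at 1.51. Immediate early genes had a median of 0.19, with FOS at 0.72 and FOSB at 0.67. Angiogenesis genes had a median of 0.11, with the ligand EFNB2 at 1.02, and this median was -0.05 under the stricter filter and -0.03 without the trend, both inside the random range. The fibroblast and WNT medians also came inside it under the stricter filter, at 0.11 and 0.07 with percentiles 97.2 and 89.2, and the angiogenesis median with no filter, at 0.08 and 96.9.

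Cholesterol synthesis genes were lower, with a median of -0.30, 14 of 16 below 0 and the sterol oxidase MSMO1 at -0.78. Genes of the unfolded protein and ATF4 response had a median of -0.20, with DDIT3 at -0.57, p53 target genes -0.15, with RRM2B at -0.63, and smooth muscle genes -0.14, with TAGLN at -0.58 but ACTA2 at 0.52, and -0.0057, inside the random range, without the trend. In the direction of the small RNA genes, whose medians were 0.61 and 0.75 in this pair, histone genes had a median of 0.67, with 15 of 21 higher by 1.5-fold and H4C2 at 1.49. Genes of oxidative phosphorylation stood at 0.22, with the small subunits COX7B at 0.90 and NDUFA1 at 0.76, and ribosomal protein genes at 0.10, inside the range at 0.06 and percentile 96.3 when a gene's probe sets were averaged. S phase genes also stood at 0.10, with 0 of 24 past 1.5-fold.

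The other lists lay inside the random range. Their medians were 0.05 for early mesoderm, -0.09 for neuroectoderm, 0.03 for endothelial, 0.09 for blood, 0.04 for adhesion, 0.02 for Notch, 0.05 for HOX, -0.01 for NF-kB, -0.07 for interferon, -0.05 for G2/M, -0.06 for hypoxia and -0.05 for reference genes. The 154 genes that entered the pair from the 200 highest in the day 8 control against the HUVEC control had a median of 0.07, outside their random range, and the corresponding 105 HUVEC genes -0.01, inside it. Of 13294 genes, 80 were higher and 5 lower by 2-fold, and 278 and 128 by 1.5-fold. The central 95% of differences spanned -0.46 to 0.53, and that of 5100 dim genes spanned -0.38 to 0.52, with 15 of those at 2-fold.

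The day 8 pair asked what lowering ALIEN did to vascular progenitors. ALIEN, taken as the lncRNA LINC00261, had 0 probe sets named for it, so the level of the targeted RNA was not analysed here. Its neighbour FOXA2, an endoderm transcription factor, was at 7.34 in the control and 7.42 with the shRNA. By list median, endothelial and blood genes were lower on the ALIEN array, and trophoblast and fibroblast genes were higher, though few blood and fibroblast genes passed 1.5-fold. The embryonic globins HBE1 and HBZ were at -2.12 and -1.45, and the fatty acid binding proteins FABP3 and FABP4 at -1.98 and -1.16. The integrin subunit ITGB6 was higher, from 6.45 to 8.95, and TDO2, which degrades tryptophan, was 2.25 higher, LIX1 2.23 and the growth factor TGFB2 1.83.

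Further genes with high differences were OLR1 at 1.79, the keratin KRT7 at 1.78, LCP1 at 1.78, SEMA3C at 1.74, CXCL14 at 1.73, SPON1 at 1.71, the WNT regulator DKK2 at 1.69 and the fibroblast growth factor receptor FGFR2 at 1.66. Further low values were those of SUMO1P3 at -1.83, TMSB15A at -1.47, the acid-sensing receptor GPR4, from 9.33 to 7.93, the histone H2AC14 at -1.34, PELO at -1.22, GNG11 at -1.19 and FIGNL2 at -1.18. The variant U1 small nuclear RNA gene RNVU1-15 was at -1.20, in the direction of the small RNA genes of this pair.

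Endothelial genes had a median of -0.67, with 26 of 27 below 0 and 17 lower by 1.5-fold. They included PROCR, the protein C receptor, at -1.15, the junction protein ESAM at -1.03, the receptor TIE1 at -0.99 and ICAM2 at -0.87. Blood genes had a median of -0.29, with 10 of 12 below 0 but only 2, HBE1 and HBZ, lower by 1.5-fold. Notch and arteriovenous genes stood at -0.21, with NRARP at -0.83, the arterial connexin GJA4 at -0.76 and the ligand DLL4 at -0.73, but NOTCH2 at 0.65. Angiogenesis genes stood at -0.17, with 4 lower and 3 higher by 1.5-fold, and their largest differences were MET at 1.24 and THBS1 at 1.15. HOX genes stood at -0.33 over 14 genes, with HOXB8 at -0.95 and HOXB5 at -0.89. After the trend with the H1 pair across genes was removed, the HOX median was -0.10, inside the random range. That value covers only genes that entered both pairs, and 5 HOX genes entered the H1 pair. The loss of members and the trend cannot be told apart in it. Endoderm genes stood at -0.23, where HHEX at -1.13, CXCR4 at -0.79 and SOX17 at -0.75, all also used by endothelial cells, were lower by 1.5-fold, and the median was 0.01 with no filter on dim genes and 0.07 without the trend, both inside the range. Neuroectoderm genes had a median of -0.25, although MAP2 was 1.00 higher, and -0.13, inside the range, with no filter.

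Trophoblast and amnion genes had a median of 0.37, with 5 of 12 higher by 1.5-fold, among them KRT7, VTCN1 at 1.44 and TFAP2A at 1.02. Without the trend with the H1 pair the median was 1.23. Pearson's r between the pairs was -0.40 and these genes had a median of 0.97 in H1, so the adjustment itself raises this value. Fibroblast and matrix genes had a median of 0.28, with 21 of 23 above 0 but 4 higher by 1.5-fold, among them POSTN at 1.61 and DCN at 1.10. WNT pathway genes stood at 0.25, with WNT5A at 0.85, and adhesion genes at 0.23, with the epithelial cadherin CDH1 at 1.14 and ITGB4 at 1.08. Both came inside the range under the stricter filter, with medians of 0.22 and 0.21 at percentiles 95.6 and 96.9, and the WNT median also without the trend, at 0.15 and 97.1. Genes of G2/M stood at 0.23, with 19 of 25 above 0 and 0 past 1.5-fold. Smooth muscle genes had a median of 0.19 at percentile 94.7 of their random lists, inside the range, with ACTA2 at 1.63, MYOCD, a master coactivator of smooth muscle genes, at 1.13, TAGLN at 1.06 and ACTG2 at 1.01. Histone genes had a median of -0.59, with 10 of 19 lower by 1.5-fold, in the direction of the small RNA medians of -0.57 and -0.79, and a median of -0.24 without the trend. Immediate early genes stood at -0.21, with IER2 at -0.61, and cholesterol synthesis genes at -0.16.

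Inside the random range were pluripotency at 0.11, early mesoderm at -0.14, cardiac at -0.01, TGF-beta and BMP at 0.11, NF-kB at 0.06, interferon at -0.10, p53 at 0.06, S phase at 0.13, hypoxia at 0.07, the unfolded protein and ATF4 response at -0.01, ribosomal proteins at -0.06, oxidative phosphorylation at -0.05 and reference genes at 0.07. Of genes high in H1 against HUVEC, 152 entered with a median of 0.27, 36 higher and 5 lower by 1.5-fold, and of genes high in HUVEC against H1, 153 entered with a median of -0.12, 18 higher and 30 lower. The second median was -0.31 with 100 genes per list and -0.066 after centring. Of 13303 genes, 105 were higher and 41 lower by 2-fold, and 546 and 304 by 1.5-fold. Without small RNA genes, an alternative chosen after seeing the data, 21 were lower by 2-fold. The central 95% of differences spanned -0.57 to 0.70, and that of 5091 dim genes spanned -0.43 to 0.50, with 17 of those at 2-fold.

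In HUVEC, the pair asked what lowering PUNISHER did to differentiated endothelial cells. PUNISHER, also known as AGAP2-AS1, had 0 probe sets named for it, and its level was not analysed here. Among its neighbours, AGAP2 was equal on both arrays at 7.19, TSPAN31 was at -0.29, OS9 at -0.36 and the cyclin-dependent kinase CDK4 at -0.57, from 12.19 to 11.62. By list, cell division genes were lower on the PUNISHER array, and interferon genes were higher. The small heat shock protein CRYAB was 4.43 higher, AMTN, a protein of tooth enamel attachment, 4.32, HAPLN1, a hyaluronan link protein, 3.92, and the matrix protein POSTN 3.62, from 7.45 to 11.07. The mitotic kinase PLK1 was at -1.92, the mitotic kinesin KIF20A at -1.85, the checkpoint kinase BUB1B at -1.81 and LYVE1 at -2.30, from 12.53 to 10.22.

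SHISA3, SLC46A3, RSPO3, the activin subunit INHBA, the cyclin CCND2, the integrin subunit ITGA4, BEX1 and C5orf46 were 3.15, 3.01, 2.89, 2.75, 2.68, 2.66, 2.58 and 2.54 higher. The linker histone H1-4 was at -2.39, RASSF2 at -1.96, RGS7BP at -1.90, the serine synthesis enzyme PHGDH at -1.86, the pericyte regulator RGS5 at -1.86, SEMA6A at -1.81, ADAMTS18 at -1.80 and KIAA0040 at -1.72.

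All 25 measured G2/M genes were lower, with a median of -1.19 and 22 past 1.5-fold. S phase genes had a median of -0.77, with 15 of 25 lower by 1.5-fold, among them GINS1 at -1.52 and the helicase subunit MCM7 at -1.45. Histone genes had a median of -0.52, with 9 of 21 lower, against the direction of the small RNA medians of 1.05 and 0.72. Interferon response genes had a median of 0.69, with 13 of 21 higher by 1.5-fold and 0 lower. IFI27 was at 1.89, SAMD9 at 1.73, the antiviral protein IFIT1 at 1.63 and the antiviral GTPase MX1 at 1.28. NF-kB response genes stood at 0.14, with the chemokines CXCL1 at 1.35 and CXCL8 at 1.00, and at 0.0073 with no filter on dim genes.

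Endothelial genes had a median of -0.51, with 23 of 29 below 0, 11 lower and 3 higher by 1.5-fold. The clotting factor VWF was at -1.30 and the matrix glycoprotein MMRN2 at -1.10, while the sialomucin EMCN was 1.42 higher. Angiogenesis genes stood at -0.21, and Notch genes at -0.14, with DLL4 at -1.41, MFNG at -1.08 and HEY2 at 1.17. Genes of hypoxia and glycolysis stood at -0.14, with LDHA at -0.77. The Notch median came inside the random range under the stricter filter, at -0.16 and percentile 2.65, and without genes of equal value, at -0.15 and 4.78, as did the hypoxia median in the latter case, at -0.15 and 5.07, although these medians were no smaller in size. Smooth muscle genes had a median of 0.16, with 3 of 14 higher and 2 lower by 1.5-fold, TAGLN at 1.99, CNN1 at 1.92 and RGS5 at -1.86, and the median was 0.00, inside the range, with no filter on dim genes. Fibroblast and matrix genes stood at 0.14, with 3 of 20 higher, POSTN, the protease FAP at 2.28 and LOX at 0.95, and at 0.046 with no filter. TGF-beta and BMP response genes stood at 0.12, with the BMP antagonist GREM1 at 1.94, TGFB2 at 1.79 and TGFBI at 1.49. Immediate early genes stood at 0.05, with JUNB at 0.58, and at 0.16 under the stricter filter and 0.18 without genes of equal value.

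Medians of 0.00 were found for pluripotency, early mesoderm, endoderm, trophoblast, cardiac, adhesion, WNT and p53 genes, and the remaining lists inside the random range were neuroectoderm at 0.01, HOX at 0.01, blood at -0.06, cholesterol synthesis at 0.06, the unfolded protein and ATF4 response at -0.08, ribosomal proteins at -0.07, oxidative phosphorylation at -0.01 and reference genes at -0.11. Both lists that set the day 8 control apart from the H1 control had medians of 0.00, but with 100 instead of 200 genes per list they were 0.07 for the genes higher at day 8 and -0.06 for those lower, both outside the random range. Of 13395 genes, 237 were higher and 167 lower by 2-fold, and 622 and 625 by 1.5-fold. Without small RNA genes, 154 were higher by 2-fold. The central 95% of differences spanned -0.77 to 0.84, and that of 4999 dim genes spanned -0.23 to 0.35, with 14 of those at 2-fold.

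**Figure D2:**
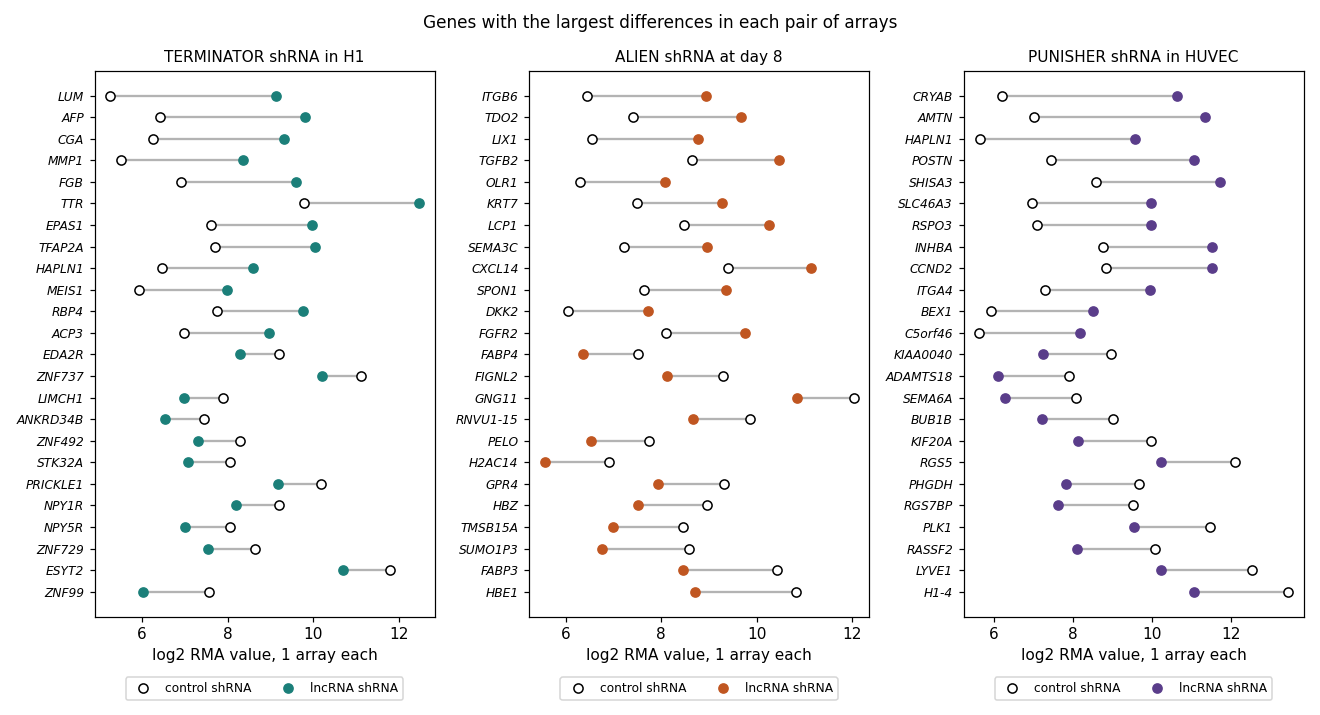
Open circles show the control shRNA array and filled circles the lncRNA shRNA array, in log2 RMA values, for the 12 genes with the highest and the 12 with the lowest differences in each pair, 1 array per circle. On the TERMINATOR array LUM stood at 9.13 against 5.26, and on the PUNISHER array LYVE1 stood at 10.22 against 12.53.

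**Figure D3:**
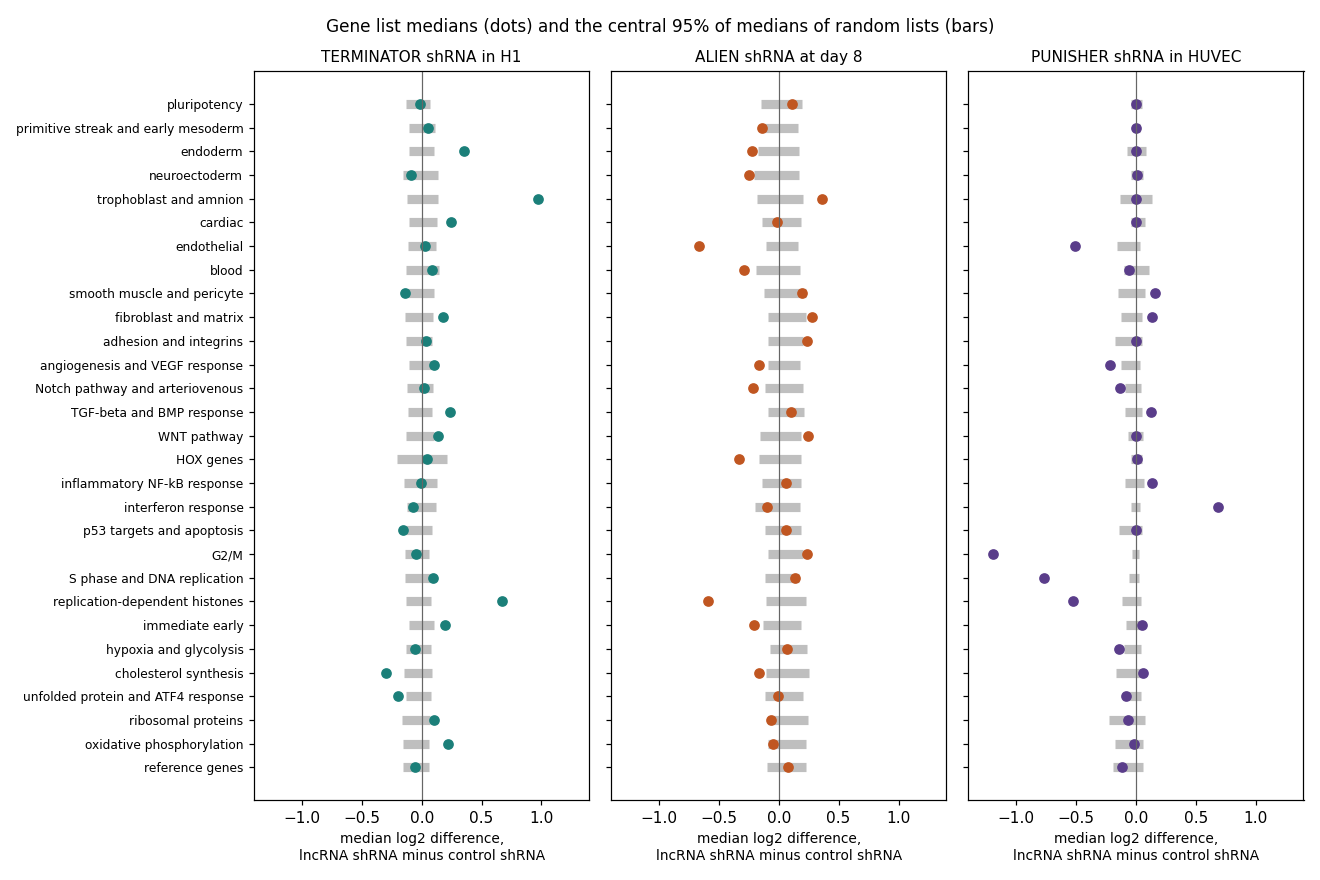
Dots show the median log2 difference of each gene list and grey bars the central 95% of the medians of 10000 random lists matched on expression, for the 3 pairs. The dot farthest from its bar was that of trophoblast and amnion genes at 0.97 for TERMINATOR, of endothelial genes at -0.67 for ALIEN and of G2/M genes at -1.19 for PUNISHER.

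The 3 pairs shared no array, and the genes at 1.5-fold were compared among them. Genes past 1.5-fold in opposite directions were not counted, so an excess over independent lists does not by itself show a shared response. TFAP2A was higher in all 3 pairs, at 2.34, 1.02 and 0.65 in the order TERMINATOR, ALIEN and PUNISHER, and TGFB2 at 1.47, 1.83 and 1.79, and these were 2 genes where independent lists give 0.271. In HUVEC, TFAP2A went from 6.43, under the control array's 40th percentile of 6.58, to 7.07, so its PUNISHER difference rests on a dim control value. The endothelial lipase LIPG was lower in all 3, at -0.62, -0.59 and -0.94, against 0.086 for independent lists. Between ALIEN and PUNISHER, 52 genes were higher in both, where independent lists give 18.1, including ACTA2, TAGLN, POSTN and GREM1, and 32 were lower in both, where independent lists give 13.0. The 32 included 7 endothelial genes, ESAM, FLI1, ICAM2, MMRN2, NOS3, TIE1 and VWF, and 4 genes of the histone list.

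Between TERMINATOR and ALIEN, 19 genes were higher in both, where independent lists give 9.05, among them the trophoblast genes CGA, TFAP2A, VGLL1 and VTCN1, and 1 was lower in both, against 2.12. Between TERMINATOR and PUNISHER, 99 were higher in both, against 9.54, and 17 lower in both, against 4.39. Without small RNA genes, 26 were higher in both, against 4.64. Across genes, which are not independent replicates, Pearson's r of the differences was -0.40 between TERMINATOR and ALIEN, 0.22 between TERMINATOR and PUNISHER and -0.14 between ALIEN and PUNISHER, and -0.36, 0.13 and -0.07 without small RNA genes.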

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

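All tests of an explanation in this part were chosen only after the results were seen. The differences between pairs below were not tested, since each group has 1 array, and the targets, the cells and the arrays all differ between the pairs.

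Several gene lists stood outside the random range on opposite sides in different pairs. Endoderm genes were higher on the TERMINATOR array and lower on the ALIEN array, with medians 0.58 apart, although the ALIEN median was 0.01 with no filter on dim genes and 0.07 as residuals on the other pair, both inside the random range. Immediate early and histone genes differed in the same directions, 0.40 and 1.26 apart. As residuals on the other pair, the histone medians shrank to 0.57 and -0.24, and the TERMINATOR immediate early median to 0.12, still outside the random range. The histone medians also went in the direction of the small RNA genes in both pairs. Smooth muscle genes were higher on the PUNISHER array and lower on the TERMINATOR array, 0.30 apart, but the first median was 0.00 with no filter and the second -0.0057 as residuals, both inside the range. The angiogenesis and S phase medians were above the random range on the TERMINATOR array and below it on the PUNISHER array, 0.32 and 0.87 apart. On the TERMINATOR array 0 of 24 S phase genes passed 1.5-fold, and the TERMINATOR angiogenesis median was -0.05 under the 60th percentile filter and -0.03 as residuals, inside the range, and also inside it with no filter. For G2/M genes the ALIEN and PUNISHER medians were 1.43 apart, higher in the first and lower in the second.

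Probe sets left out of the gene comparisons also differed. Of those without a gene symbol, the 4203 with the lowest identifiers were counted apart and without the filter. Among the other 2480, 2592 and 2613 that passed the filter, 46, 13 and 123 were higher by 2-fold on the TERMINATOR, ALIEN and PUNISHER arrays. In the same order 1, 66 and 43 were lower. The 4203 went mostly the other way, with 51, 198 and 74 higher and 117, 86 and 558 lower. Among those with several symbols that passed the filter, 13, 4 and 26 were higher and 1, 19 and 11 lower.

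Small nucleolar RNA genes were higher on the TERMINATOR and PUNISHER arrays and lower on the ALIEN array, with medians of 0.61, 1.05 and -0.57. Most of these RNAs are cut from introns of host genes, but the host genes' median was far smaller than the small nucleolar RNA median in 3 of 3 pairs, at -0.03, 0.00 and 0.01. In HUVEC 10 of 32 host genes were higher and 13 lower, and the others were equal. This argues against a shift in the RNA level of the host genes. Their transcription was not measured and stays open. After loess the medians were 0.64, 1.05 and -0.57, so a scaling that moves genes of like expression together did not account for them. They stayed outside the random range in 3 of 3 pairs. This decides nothing more, since the random lists, matched on expression, are rescaled with them. Small nuclear RNA genes, which have promoters of their own, shifted with them in 3 of 3 pairs, but microRNA genes, at 0.03, 0.00 and -0.09 in the same order, stayed inside the random range in each pair. Unequal recovery of short RNAs between preparations therefore stays open, since it was not tested whether the microRNA probe sets read short RNAs or their long precursors, and so does an effect of the lncRNAs, which was not tested because each shRNA was prepared once.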

How the results depend on the processing

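The tests chosen only after the results were seen are the counts without small RNA genes, the residuals on the other pair and the medians without genes of equal value. No paired analysis was possible because each group has 1 array and the labels give no shared replicate numbers. Of 571 summary values recomputed under an alternative, 464 kept their sign and moved little. The 117 values given here are the others and the list medians of control comparisons that changed sign, and 14 of the 117 changed sign. The 464 include 53 for random lists without matching, most of them list medians, which that alternative cannot change. Each of the 24 genes named for a lncRNA pair and the 16 named for a control comparison kept its sign and 1.5-fold under all 3 other scalings. These genes were picked for the largest differences, so this was nearly fixed in advance. Under the 60th percentile filter, 8 of the 24 for TERMINATOR and 4 of the 24 for ALIEN no longer entered. No list of the lncRNA pairs came inside the random range under another scaling. A scaling also moves the matched random lists, so it could hardly change this. Under other alternatives 13 lists came inside the range, in 18 cases: 7 for TERMINATOR, 7 for ALIEN and 4 for PUNISHER. Signal over background was not given, so how far dim genes are limited by it is unknown, and where no construction shows the reason the cause was not tested.

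Scaling mattered most between cell states, whose array medians differ. With each array centred on its median, 1375 genes were higher and 2114 lower at day 8 against H1, and 2606 and 1848 in HUVEC against H1. Quantile normalization gave 1582 and 1847, and 2106 and 2063. Loess gave 1568 and 1698, then 2126 and 2218, and 1168 higher in HUVEC against day 8. Medians of day 8 against H1 also changed sign. Notch genes, at -0.15 as deposited, stood at 0.23 centred, 0.43 quantile normalized and 0.46 after loess, and WNT genes, at -0.10, stood at 0.28, 0.44 and 0.45.

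Among the lncRNA pairs, quantile normalization gave 0.75 for TERMINATOR histones. For PUNISHER it gave -0.46 for endothelial, 0.21 for smooth muscle, -0.18 for angiogenesis, -0.10 for Notch, 0.63 for interferon, -1.13 for G2/M, -0.72 for S phase, -0.45 for histones and -0.11 for hypoxia. Loess gave -0.74 for PUNISHER S phase. For the genes of the day 8 control against HUVEC, the TERMINATOR median of 0.07 was 0.046 centred, 0.10 after loess and 0.18 with 100 genes per list. ALIEN medians of the H1 genes against HUVEC were 0.32 centred, 0.22 with no filter and 0.32 with 100 genes. Those of the HUVEC genes were -0.066 centred, -0.17 quantile normalized, -0.16 after loess, -0.073 with no filter, -0.075 under the 60th percentile filter and -0.31 with 100 genes.

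The filter on dim genes changes which genes enter a list. With no filter, TERMINATOR medians were 0.80 for trophoblast and 0.18 for cardiac genes, and ALIEN medians 0.012 for endoderm, with the sign changed, -0.13 for neuroectoderm and 0.15 for WNT. PUNISHER medians were 0.00 for smooth muscle, 0.046 for fibroblast, -0.12 for angiogenesis, 0.077 for TGF-beta, 0.0073 for NF-kB and 0.66 for interferon. Inside the random range with no filter were TERMINATOR angiogenesis, ALIEN endoderm and neuroectoderm, and PUNISHER smooth muscle. Among control medians as deposited, that of early mesoderm at day 8 against H1 changed sign, from 0.12 to -0.058. So did that of trophoblast genes in HUVEC against H1, from 0.77 to -0.15. The early mesoderm median of 0.50 given in the Results is on the centred scale, to which this change does not refer.

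Under the 60th percentile filter, 3 genes were lower by 2-fold for TERMINATOR. Its medians were 1.49 for endoderm, 1.79 for trophoblast, 0.33 for cardiac, -0.20 for smooth muscle, 0.11 for fibroblast, -0.047 for angiogenesis, with the sign changed, 0.17 for TGF-beta and 0.072 for WNT. ALIEN medians were -0.51 for endoderm, -0.36 for neuroectoderm, -0.41 for blood, -0.34 for Notch and -0.47 for HOX genes. PUNISHER medians were 0.39 for smooth muscle, -0.30 for angiogenesis, 0.19 for TGF-beta, -1.25 for G2/M, -0.82 for S phase, -0.57 for histones, 0.16 for immediate early and -0.20 for hypoxia. As deposited, Notch genes of day 8 against H1 changed sign from -0.15 to 0.13, and trophoblast genes of HUVEC against day 8 from -0.58 to 0.068. Overlaps were 9 genes higher for TERMINATOR and ALIEN, where independent lists give 6.11, and 1 in all 3, against 0.188. Inside the random range under this filter were fibroblast, angiogenesis and WNT genes for TERMINATOR, adhesion and WNT genes for ALIEN and Notch genes for PUNISHER.

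As residuals on the other pair, TERMINATOR medians were 0.16 for endoderm, 1.22 for trophoblast, 0.36 for cardiac, -0.0057 for smooth muscle, -0.028 for angiogenesis, with the sign changed, and 0.15 for TGF-beta. They were 0.57 for histones, 0.12 for immediate early, -0.39 for cholesterol, -0.12 for the unfolded protein response and 0.15 for oxidative phosphorylation. ALIEN residuals were 0.073 for endoderm, with the sign changed, 1.23 for trophoblast, -0.54 for endothelial, 0.39 for fibroblast, 0.15 for WNT, -0.10 for HOX, -0.24 for histones and -0.27 for cholesterol. Since r between these pairs was -0.40, the adjustment raises a residual where the list was higher in the other pair. It lowers one where the list was lower there. Residuals also leave out genes that did not enter both pairs, so a residual median can differ because members dropped out. Of the HOX genes, 14 entered the ALIEN pair and 5 the TERMINATOR pair. Smooth muscle and angiogenesis residuals for TERMINATOR and endoderm, WNT and HOX residuals for ALIEN lay inside the random range. With the mean of a gene's probe sets, TERMINATOR ribosomal proteins did so.

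Without genes of equal value, PUNISHER medians were 0.41 for smooth muscle, -0.30 for angiogenesis, 0.22 for TGF-beta, 0.20 for NF-kB, -0.82 for S phase and 0.18 for immediate early, and Notch and hypoxia genes came inside the range. Without small RNA genes, 21 genes were lower by 2-fold for ALIEN, 154 were higher for PUNISHER and 26 were higher in both TERMINATOR and PUNISHER. At 2-fold, which fewer genes reach, the overlaps were 6 higher, against 0.381 for independent lists, and 0 lower for TERMINATOR and ALIEN, 20, against 0.857, and 0 for TERMINATOR and PUNISHER, 11, against 0.929, and 2, against 0.435, for ALIEN and PUNISHER, and 1, against 0.003, and 0 for all 3.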

Other observations

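All tests and gene choices in this part were made after the results were seen.

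Some protein-coding genes with short transcripts, picked for this pattern, differed in the direction of the small RNA genes in all 3 pairs. COX7B, a small subunit of cytochrome c oxidase, was at 0.90, -0.95 and 0.99 on the TERMINATOR, ALIEN and PUNISHER arrays, and NDUFB6, a small subunit of complex I, at 0.45, -0.88 and 0.79. B2M, the light chain of MHC class I, was at 0.45, -0.88 and 0.65, and the ribosomal protein gene RPL35 at 0.48, -0.64 and 0.51. Of the oxidative phosphorylation list 8 of 20 genes and of the ribosomal protein list 5 of 19 went in these directions in all 3 pairs, and NDUFB3, another small subunit of complex I, did not, at 0.65, -0.28 and -0.74. Transcript length was not tested as a property of all genes. The histone list followed this order on the TERMINATOR and ALIEN arrays, at 0.67 and -0.59, and stood at -0.52 on the PUNISHER array, where the cell cycle lists were also below 0.

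Some vascular and contractile genes, picked after their values were seen, went the same way on the ALIEN and PUNISHER arrays, while Pearson's r across all genes of these pairs was -0.14. ESAM was at -1.03 and -1.07, TIE1 at -0.99 and -0.75 and NOS3, the endothelial nitric oxide synthase, at -0.65 and -0.93, while ACTA2, the actin of smooth muscle, was at 1.63 and 0.63, TAGLN at 1.06 and 1.99 and POSTN at 1.61 and 3.62. EMCN was at -0.85 in the first pair and 1.42 in the second, so the endothelial genes did not all go the same way.

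Some matrix and contractile genes, POSTN, FAP, TAGLN and CNN1 among them, stood higher on the PUNISHER array. Most list members did not: 3 of 20 fibroblast and matrix genes were higher by 1.5-fold. Of 14 smooth muscle genes, 3 were higher and 2 lower by 1.5-fold, with RGS5 at -1.86. Fibroblasts in the culture would bring their abundant transcripts, which had a median of 0.0186 over the 8 that entered the pair. That median decides little, since COL6A2 and PDGFRB had exactly equal values and SPARC and BGN stood at 13.75 and 13.45 in the control. COL1A1 went from 8.04 to 8.32, COL1A2 from 7.77 to 7.96 and COL3A1 from 7.21 to 7.355. Fibroblasts were therefore not excluded, although these collagens rose far less than POSTN, at 3.62. The transcripts of that list that did not enter the pair did not rise either. LUM, DCN and COL6A3 were equal on both arrays, at 4.03, 4.11 and 6.18, and THY1 went from 6.49 to 6.46. Such dim values, most of them equal for an unknown reason, give no sign of added fibroblasts but cannot exclude them. A lower share of endothelial cells was not excluded: their markers had a median of -0.51, with 11 of 29 lower by 1.5-fold, while EMCN, CD34 and THBD were higher by 1.5-fold, and without replicates these go no further. A change of state within the endothelial cells and a difference between the cultures also stay open and were not tested.

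On the HUVEC arrays, 35.6% of probe sets had exactly equal values. One array deposited under both labels is excluded by 404 genes at or beyond 2-fold. A floor set on dim probe sets is argued against by the 8.26% of genes with equal values among the brightest 1840, although the share among the dimmest 1840 was 69.2%. The most repeated value occurred 88 and 79 times on the HUVEC arrays and 9 times on each of the others, a ratio of at least 8.78, but these arrays held 22867 and 24105 distinct values, and repeats within an array do not show why the same probe set had equal values on both. Whether a coarse grid of values produced them stays open.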
